A study of Felis catus with 8 samples.

How the data were processed

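Liver RNA of male cats was measured on 8 Affymetrix human whole-transcript arrays (HuGene 1.0 ST), 2 for each of 4 diets. Per the labels' protocols, 250 ng of total RNA was made into biotin-labelled DNA for hybridisation, and 4 to 5 livers per diet were used for RNA; 2 arrays per diet were analysed here. The labels number each array as a different cat, but do not say whether RNA was pooled. The deposited values are intensities per exon-level probe set on a linear scale, already normalized: GCRMA, Partek and the human build hg19 are named, per the submitters' processing notes, without versions, roles or order. The labels name no filter before deposit. The lowest intensity was between 2.22 and 2.3 on each array and the highest between 21603 and 22966, so the values were taken as linear and log2 transformed here. Cat RNA on human probes lowers the signal of transcripts that differ in sequence, and a sequence difference between cats under a probe set changes its value with no change in expression.

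Gene names came from the platform annotation of the array, which names 1 gene for 224320 probe sets, several for 10159 and none for 22622. Symbols are those of that annotation, so some are old (KBTBD10, SHFM1, SC4MOL). Probe sets whose mean over the 8 arrays exceeded the median of all probe sets (log2 2.43, intensity 5.38) were kept, 128550 in number, and the 111624 kept probe sets with 1 gene were averaged per gene. This gave 17910 genes, with a median of 5 kept probe sets, of which 2000 rested on 1. A table of cat genes (assembly F.catus_Fca126_mat1.0) was used for names only: 13566 of the tested genes (75.7%) had a symbol or synonym in it. No genome was used and no coordinates are given. Some genes are not reported here.

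Each comparison was a contrast in a 4-group model fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), two-sided, with Benjamini-Hochberg adjustment over the 17910 genes and a threshold of 0.05. The spread was pooled over the 4 diets, with 4 residual degrees of freedom and a prior of 5.01. Main effects average the 2 differences between diets, so each sets 4 arrays against 4. The interaction is the MSG effect on the trans-fat/HFCS base minus that on chow. The other 3 contrasts set each diet against control with 2 arrays each. Errors beside log2 changes are the moderated standard errors of limma.

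Before the data were examined, 35 gene lists were fixed: cholesterol synthesis and uptake, fatty acid and triglyceride synthesis, fatty acid oxidation and PPARA targets, lipid droplets, lipoproteins, bile acids, fructose and glucose breakdown, gluconeogenesis and glycogen, insulin and IGF, glutamate and glutamine, urea cycle and amino acids, drug metabolism, oxidative stress, endoplasmic reticulum stress, heat shock, immediate early genes, acute phase, inflammatory signalling, interferon response, fibrosis and stellate cells, macrophages, lymphocytes, neutrophils, erythroid cells, endothelium, cholangiocytes, hepatocytes, adipocytes, pancreas, cell cycle, circadian clock, oxidative phosphorylation, ribosomal proteins, proteasome and coagulation. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists, with an estimated correlation and with fry beside it. fry tests whether a list's genes move one way, without comparing it with other genes. Camera compares a list with the other genes. With the preset correlation its degrees of freedom come from the number of genes, and with an estimated correlation from the arrays. Its p-values can therefore be far larger with an estimated correlation even where that correlation is near 0. The rule for naming genes was also fixed before: for main effects the 12 increases and 12 decreases largest in log2 change among those past the threshold, for other comparisons 5 and 5, with the genes of smallest p filling up to 5 or 3 where fewer passed. For each list described, up to 4 members with the smallest p are named. Genes with 1 kept probe set, uncharacterised loci, olfactory receptors and non-coding RNAs were counted but passed over. A further 3 lists of skeletal muscle and smooth muscle genes were written after muscle genes were noticed among the calls.

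The steps were tested on simulated data with 17910 genes drawn from the real means and the variances as moderated by limma. Moderated variances are more even than the observed ones, and changes were added to whole genes. Recovery in the real data may therefore be lower. For the trans-fat/HFCS main effect, 94% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold were called, and for the MSG main effect 99% and 100%. For the MSG diet against control, 52% and 99% were called, and for the interaction 7% and 95%. False calls numbered 17, 17, 14 and 4 in that order. In 35 simulated lists of 20 genes, a list shifted by 0.5 on the log2 scale was called by camera, and also with an estimated correlation (adjusted p = 0.013), and no other list was. Genes were drawn independently of each other, so the simulation does not show how the list tests perform on correlated genes.

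Alternatives fixed before the data were examined changed the filter on dim probe sets, the summary per gene, the normalization, the variance model, array weights, the model, the threshold, the set test and the arrays used, and included the replicate number as a block. Alternatives added later left out the trans-fat/HFCS diet, the skeletal muscle genes, genes with no cat symbol and genes with 1 kept probe set. The outlier test needs at least 4 samples per group, so it was not run on groups of 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.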

Results

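Gene expression was measured in snap-frozen liver of male domestic cats aged 9 months, with 2 arrays for each of 4 diets. The control diet was a standard cat chow. The MSG diet was that chow with 1.125% monosodium glutamate (MSG), a flavour enhancer. The trans-fat/HFCS diet held 8.6% trans fat and 24% high-fructose corn syrup (HFCS), and the combined diet held trans fat, HFCS and MSG. Dams ate their diet from 3 weeks before mating until the end of nursing, and the male offspring were weaned onto the diet of their dam. The labels call the 2 arrays of a diet biological replicates and number the arrays as 8 different cats, but name no litters and do not say whether RNA was pooled. The p-values of single genes therefore measure the spread between arrays, whether an array held 1 cat or a pool and whether or not cats of 1 diet shared a dam. Those of camera with the preset correlation set the genes of a list against the other genes, and do not measure that spread. Cat RNA was hybridised to a human gene array, so a probe set reads a cat transcript only as far as the sequences match. Median intensity lay between 5.25 and 5.28 on the 8 arrays, and the number of arrays limits the precision. Of 257101 probe sets, 128550 lay above the median, and those with a single gene name gave 17910 genes to test. The first principal component held 35.4% of the variance and put all 4 arrays of the diets with trans fat and HFCS on the side opposite the other 4 arrays. Gene values of 2 arrays of the same diet correlated across genes with r between 0.946 and 0.968, and those of different diets with r between 0.917 and 0.956. No pair of arrays held identical values.

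The first comparison asked how liver expression differed between cats on trans fat and HFCS and cats without them, averaged over the diets with and without MSG (4 arrays against 4). CYP7A1, the rate-limiting enzyme of bile acid synthesis, fell by 1.57 on the log2 scale (SE 0.13), a level 2.97-fold lower. Its mean log2 intensity was 5.39 ± 0.07 (SD, n = 2) on the control diet, 3.73 on both trans-fat/HFCS arrays and 4.67 ± 0.24 (SD, n = 2) on the combined diet. FKBP5, a co-chaperone of the glucocorticoid receptor, rose 3.1-fold (log2 1.63, SE 0.14), and VNN1, a pantetheinase and target of the lipid-sensing receptor PPARA, rose 3.49-fold (log2 1.80, SE 0.25). The haemoglobin-binding acute-phase protein HP was 3.05-fold lower (log2 -1.61, SE 0.22), the mean of probe sets at -2.64 and -0.58. CEL, a bile salt-dependent lipase, was 3.07-fold lower (log2 -1.62, SE 0.15). Without the filter on dim probe sets VNN1 rose by 0.41 and did not pass (adjusted p = 0.062 in limma), and with its brightest probe set CEL did not pass (log2 -1.30, adjusted p = 0.086).

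In all, 1372 genes passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, 796 higher and 576 lower with trans fat and HFCS. Of these, 1028 differed by at least 1.5-fold, and the median log2 change of all tested genes was 0.02. Besides FKBP5 and VNN1, the largest increases among genes open to naming were those of BAG5 (log2 1.75), ZBTB6 (1.68), MYH1 (1.68), MYL1 (1.66), NT5C (1.65), ZMAT5 (1.62), ZAR1 (1.59), DIABLO (2.82-fold), SHFM1 (1.49) and BRD9 (1.48). Besides CYP7A1, HP and CEL, the largest decreases were those of ID2B (log2 -2.39), HOXA3 (-2.02), GADL1 (-1.83), the cytokine IL19 (-1.79), ACAT2 (-1.67), MXRA8 (-1.64), FCER1G, a signalling chain of Fc receptors (-1.55), PADI4, a peptidylarginine deiminase (-1.54), and PLEKHF1 (-1.54). Adjusted p in limma for these 24 genes lay between 0.0002 for MYH1 and 0.026 for SHFM1. The skeletal muscle myosins MYH1 and MYL1 were high on both trans-fat/HFCS arrays and on no other. MYL1 stood at log2 6.47 ± 0.03 (SD, n = 2) there and at 3.33 ± 0.24 (SD, n = 2) on the combined diet. In BAG5, ZBTB6, GADL1, ID2B, DIABLO and MXRA8, 1 probe set moved over 8-fold and the other moved by at most 0.26 on the log2 scale in size. The 2 probe sets also differed in FCER1G (-2.80 and -0.30), ZAR1 (2.82 and 0.36) and SHFM1 (2.48 and 0.49), and in PADI4 1 of 3 moved by -3.45 and the others by a median of -0.59. Without the filter on dim probe sets BRD9 (0.20, adjusted p = 0.095 in limma) and PADI4 (-0.25, adjusted p = 0.086) did not pass. With the brightest probe set NT5C (1.02), MYL1 (0.56) and PLEKHF1 (-0.78) did not pass either, and DIABLO fell to 0.61 without MSG array 1 (adjusted p = 0.07). ID2B is the name of a human pseudogene of ID2, with which it shares sequence, and the probe sets of ID2 itself averaged a log2 change of -0.56 (SE 0.20, adjusted p = 0.13 in limma). Leaving out any 1 array other than combined-diet array 2 left between 436 and 867 genes, and 1232 passed without that array. Without both arrays of the trans-fat/HFCS diet, a choice made after seeing the data, the contrast of the combined diet with the MSG diet gave 228 genes.

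Camera, run in limma with a preset correlation, called the list of cholesterol synthesis lower with trans fat and HFCS (adjusted p of 3.3e-06), but not with an estimated correlation (adjusted p = 0.15). Of 20 measured members, 8 fell and none rose, with 11 lower when adjusted over the list alone, and the median member was 1.39-fold lower (log2 -0.48), or -0.28 without the filter on dim probe sets. Those that fell included DHCR7, which catalyses a last step of cholesterol synthesis (log2 -1.50, SE 0.13), the sterol isomerase EBP (-1.01, SE 0.12), the thiolase ACAT2 (-1.67, SE 0.21) and the isopentenyl diphosphate isomerase IDI1 (-0.86, SE 0.17). In the list of fatty acid and triglyceride synthesis, 7 of 22 measured members fell and none rose. Adjusted over the list alone, 9 were lower and 2 higher, and the median was -0.27. Those that fell included ACLY, which makes cytosolic acetyl-CoA (log2 -0.94, SE 0.14), MID1IP1, an activator of acetyl-CoA carboxylase (-0.79, SE 0.14), the malic enzyme ME1 (-0.64, SE 0.13) and the phosphatidate phosphatase LPIN1 (-0.57, SE 0.11). Its camera adjusted p was 0.0092 in limma, and the adjusted p = 0.26 with an estimated correlation. Without both trans-fat/HFCS arrays, where the skeletal muscle genes were high, only the combined against the MSG diet is left. There the cholesterol list had a camera adjusted p of 0.0035 in limma and the fatty acid list 0.3. The fatty acid call also ended with the 75th percentile filter (adjusted p = 0.22 in limma).

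**Figure D1:**
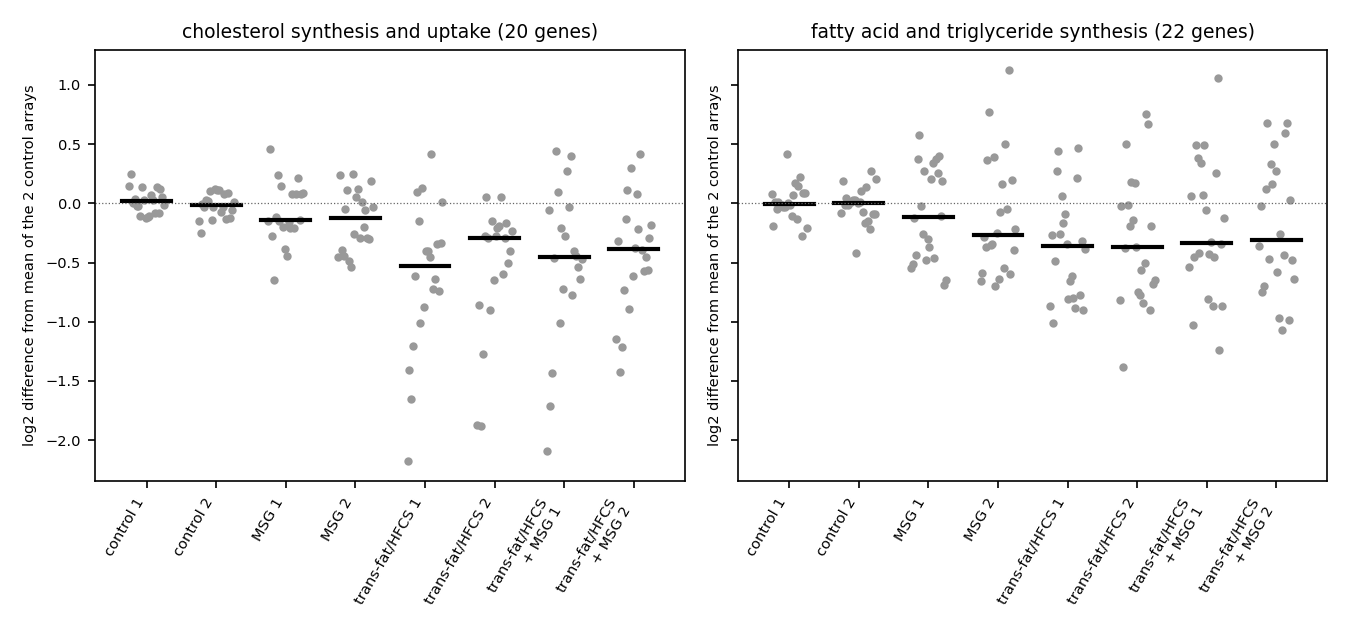
Log2 difference of each gene from the mean of the 2 control arrays (vertical axis) on each of the 8 arrays (horizontal axis), for the 20 measured genes of cholesterol synthesis and uptake (left) and the 22 of fatty acid and triglyceride synthesis (right). Grey points are genes, black bars are medians over the list.

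Averaged over both levels of MSG, camera in limma also called the fibrosis and stellate cell list (adjusted p of 0.0034) and the immediate early list (0.0042) lower. Neither was called with an estimated correlation (adjusted p = 0.25 and 0.33) or on the trans-fat/HFCS diet against control, and few members passed. Of 25 measured fibrosis and stellate cell markers, 20 had a negative change, with a median of -0.22, and 2 fell. These were the matrix protein SPARC (log2 -0.62, SE 0.11) and the growth factor receptor PDGFRB (-0.60, SE 0.13). THBS1, at -0.68 (SE 0.18), and MMP2, at -0.48 (SE 0.16), did not pass. Adjusted over the list alone, 3 were lower. Among 17 immediate early genes, which respond to signals within minutes, 3 fell and none rose, with 6 lower and 1 higher when adjusted over the list alone. DUSP1, a MAP kinase phosphatase (log2 -1.47, SE 0.12), the mRNA decay factor ZFP36 (-1.19, SE 0.12) and FOSB (-1.31, SE 0.17) fell. JUND, at -0.40 (SE 0.11), did not pass. DUSP1 differed by -0.33 (SE 0.17) between the trans-fat/HFCS diet and control and by -2.60 (SE 0.17) between the combined and MSG diets, as it rose on the MSG diet (log2 1.49). The list had a median of -0.28. Without the filter on dim probe sets the medians were -0.12 for the fibrosis list and -0.18 for the immediate early list. Without the trans-fat/HFCS arrays, which leaves the combined against the MSG diet, camera called both lists, each with an adjusted p of 0.0017 in limma. On the trans-fat/HFCS diet against control, camera gave adjusted p of 0.32 for the fibrosis list (median -0.09) and 0.19 for immediate early genes (-0.21) in limma. With the 75th percentile filter both ended, at adjusted p of 0.081 and 0.18. None of 17 measured hepatocyte markers passed, with a camera adjusted p of 0.88 in limma. None of the 35 fixed lists passed with an estimated correlation in any of the 6 comparisons.

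The effect of trans fat and HFCS was also measured on separate arrays, without MSG and with it. Of the 444 genes called for the trans-fat/HFCS diet against control, 380 (85.6%) had the same sign in the combined diet against the MSG diet. Both contrasts called 105 genes, 104 of them in the same direction, where independent lists of these sizes would share 7.36. However, both contrasts use the same estimate of spread, which can raise the number shared. Log2 changes correlated across all genes with Pearson's r = 0.43 and Spearman's rho = 0.38, although genes are not independent replicates. Among the 444 genes, the median ratio of the second change to the first was 0.46. As the 444 were picked by the first change, this ratio may be too low.

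**Figure D2:**
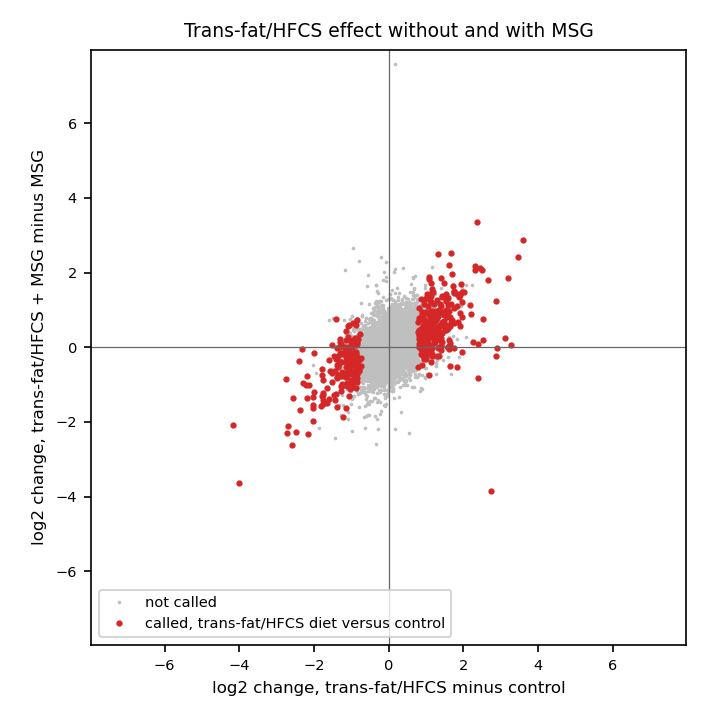
Each point is 1 of 17910 genes, with the log2 change of the trans-fat/HFCS diet against control on the horizontal axis and that of the combined diet against the MSG diet on the vertical axis. The axes share no array, and red points are the 444 genes called on the horizontal axis, of which 380 have the same sign on both axes.

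The second comparison asked what MSG did on average over both base diets (4 arrays against 4). FST, which encodes follistatin, a binding protein of activins and myostatin, rose 2.71-fold (log2 1.44, SE 0.12). DIO2, which turns thyroxine into its active form, rose 2.25-fold (log2 1.17, SE 0.12), and SLC25A25, a mitochondrial carrier of ATP-Mg and phosphate, rose 2.22-fold (log2 1.15, SE 0.13). CYP7A1 and CEL, both lower with trans fat and HFCS, were higher with MSG, by log2 0.85 (SE 0.13) and 0.93 (SE 0.15). The call of CEL ended without any 1 array (adjusted p between 0.087 and 0.19 in limma), and that of CYP7A1 without any 1 array other than combined-diet array 1 (between 0.074 and 0.19). Without the filter on dim probe sets both ended, at log2 0.34 (adjusted p = 0.23) for CEL and 0.48 (adjusted p = 0.052) for CYP7A1. EGR1, an immediate early transcription factor (log2 -1.29, SE 0.14), the phosphatase PHOSPHO1 (-1.51, SE 0.13) and the hedgehog ligand DHH (-1.38, SE 0.17) fell. On chow, MSG changed FST, DIO2 and SLC25A25 by log2 2.61, 1.94 and 2.11, and on the trans-fat/HFCS base by 0.26, 0.40 and 0.19. For CEL the values were 0.26 and 1.59, for CYP7A1 0.77 and 0.94, for EGR1 -2.04 and -0.54, for DHH -2.17 and -0.60, and for PHOSPHO1 -1.62 and -1.40. In PHOSPHO1 1 of 3 probe sets moved over 8-fold while the others had a median of -0.20, and DHH rests on probe sets at -2.65 and -0.12. With its brightest probe set EGR1 did not pass (log2 -0.39, adjusted p = 0.49 in limma).

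limma called 59 genes for MSG at a Benjamini-Hochberg adjusted p under 0.05, 8 higher and 51 lower. The 12 named decreases also included WDR86 (log2 -1.10, probe sets at -2.51 and 0.31) and 8 skeletal muscle genes: the myosins MYL1 (-1.53), MYH1 (-1.50) and MYH2 (-1.24), the actin ACTA1 (-1.49), the calcium pump regulator SLN (-1.40), KBTBD10 (-1.17), the tropomyosin TPM2 (-1.10) and MYBPC1 (-1.10). Adjusted p for the 17 named genes lay between 0.001 for MYH1 and 0.044 for CEL in limma, and none of the 17 kept its call in every setting run. The median of 11 skeletal muscle genes stood 2.50 and 2.29 above the control mean on the log2 scale on the trans-fat/HFCS arrays, and within 0.06 of that mean on the other 6. Without the trans-fat/HFCS diet, which leaves the MSG diet against control, ACTA1 (0.07), SLN (0.04) and MYBPC1 (0.15) turned sign. So did KBTBD10 with its brightest probe set (0.71) and MYBPC1 with the 75th percentile filter (0.36). With the skeletal muscle genes left out, a choice made after seeing the data, 43 genes passed. No gene list was called by camera, estimated correlation or fry, with 3 of 35 lists at an unadjusted camera p under 0.05. Among immediate early genes EGR1 and FOS fell (log2 -1.29 and -0.97), and ZFP36 (-0.73, adjusted p = 0.054 in limma) and MYC (0.65, adjusted p = 0.12) did not pass. None of the 23 measured genes of glutamate and glutamine metabolism passed. Their smallest p belonged to the glutamine synthetase GLUL (log2 -0.46, SE 0.13, adjusted p = 0.39 in limma). The count was 1 in a model of both factors without their interaction and 1 with MSG as the only factor, and lay between 15 and 39 without any 1 array other than trans-fat/HFCS array 2 (41) or combined-diet array 2 (70). The MSG effects on the 2 base diets, which share no array, correlated across genes with r = -0.02 and rho = -0.05. Of the 53 genes called on chow, 45 (84.9%) had the same sign on the trans-fat/HFCS base, with a median ratio of 0.21. As the 53 were picked by their change on chow, this ratio may be too low. Of the 32 called on that base, 14 (43.8%) had the same sign on chow. Both called 2 genes, 1 of them in the same direction, against 0.0947 for independent lists, though both contrasts use the same estimate of spread.

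Whether MSG acted differently on the 2 base diets was tested by the interaction. OSGIN2 fell with MSG on chow, from a mean log2 intensity of 6.61 ± 0.06 to 4.43 (SD, n = 2), while the trans-fat/HFCS diets stood at 4.28 ± 0.20 and 4.39 ± 0.19 (SD, n = 2) without and with MSG. Its interaction was 2.29 (SE 0.25). TMEM41A (log2 3.10, SE 0.33), the mitochondrial carrier SLC25A21 (2.16, SE 0.27), BEGAIN (1.99, SE 0.26) and the peptide transporter SLC15A3 (1.94, SE 0.27) also had a more positive MSG effect on the trans-fat/HFCS base. The glutathione transferase GSTA3 went the other way (-2.83, SE 0.37), as did the muscle genes MYL1 (-3.21), ACTA1 (-3.08), SLN (-2.89) and MYH1 (-2.85), which were high on both trans-fat/HFCS arrays alone.

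limma called 27 genes for the interaction at a Benjamini-Hochberg adjusted p under 0.05, 11 positive and 16 negative. Adjusted p for the 10 named genes lay between 0.0019 for MYL1 and 0.037 for SLC15A3 in limma. With the skeletal muscle genes left out after the data were seen, 12 passed. The interferon response list had a median interaction of -0.33, with 18 of 25 members negative and a camera adjusted p of 0.014 in limma (adjusted p = 0.44 with an estimated correlation). No member passed over all genes, and 1 was lower when adjusted over the list alone. MX2 had -1.38 (SE 0.30), IFIT3 -1.01 (SE 0.27), DDX58 -0.94 (SE 0.29) and OAS1 -1.13 (SE 0.52). In SLC15A3 and GSTA3, 1 of 3 probe sets moved over 8-fold while the others had a median of 0.27 and -0.16, and in TMEM41A and BEGAIN the medians beside 1 such probe set were 1.49 and 0.71. Without the filter on dim probe sets BEGAIN (0.97, adjusted p = 0.087 in limma) and SLC15A3 (0.59, adjusted p = 0.33) did not pass. The interferon call ended without MSG array 1 (median -0.38), trans-fat/HFCS array 2 (-0.20) or combined-diet array 2 (-0.46). It also ended with the 75th percentile filter (camera adjusted p = 0.18 in limma), without a filter on dim probe sets (median -0.15, adjusted p = 0.078) and by fry (adjusted p = 0.1).

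The MSG diet alone was set against control with 2 arrays each. FST rose 6.1-fold (log2 2.61, SE 0.17), from 4.29 ± 0.07 to 6.90 ± 0.03 (SD, n = 2). SLC25A25 rose 4.32-fold (log2 2.11, SE 0.18), DIO2 3.84-fold (1.94, SE 0.18), the nuclear receptor NR4A2 3.03-fold (1.60, SE 0.21) and DUSP1 2.81-fold (1.49, SE 0.17). The calpain CAPN13 (log2 -2.36, SE 0.33), TMEM41A (-2.30, SE 0.24), OSGIN2 (-2.18, SE 0.18), DHH (-2.17, SE 0.24) and BEGAIN (-2.07, SE 0.18) fell. In CAPN13, TMEM41A, DHH and BEGAIN 1 probe set fell over 8-fold, and the others had medians of -0.57, 0.02, -0.47 and -0.52. In NR4A2 5 of 7 probe sets rose, 2 of them over 8-fold, and with the 75th percentile filter or the brightest probe set alone it did not pass (log2 0.22 in each). CAPN13 did not pass without the filter on dim probe sets (log2 -0.40, adjusted p = 0.22 in limma).

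limma called 53 genes at a Benjamini-Hochberg adjusted p under 0.05, 9 higher and 44 lower, with adjusted p between 0.00036 for FST and 0.027 for CAPN13 among the named genes. Interferon response genes had a median change of 0.27 (0.10 without the filter on dim probe sets) with 20 of 25 positive, but no member passed over all genes and 1 did when adjusted over the list alone. IFIT3 had log2 1.18 (SE 0.19), MX2 0.74 (SE 0.21), DDX58 0.69 (SE 0.20) and IFIT2 0.56 (SE 0.23). Camera gave an adjusted p of 0.0018 in limma, and the adjusted p = 0.47 with an estimated correlation. Among 26 fatty acid oxidation genes and PPARA targets, 21 were positive with a median of 0.16 (0.06 without that filter). CPT1A, which controls fatty acid entry into mitochondria, rose by log2 1.20 (SE 0.17), also the only one when adjusted over the list alone. ACADVL (0.54, SE 0.18), ETFDH (0.52, SE 0.19) and HADHB (0.46, SE 0.19) did not pass. That list had a camera adjusted p of 0.04 in limma and an adjusted p = 0.47 with an estimated correlation. Leaving out any 1 control or MSG array left between 14 and 20 genes. The interferon call ended without MSG array 1 (adjusted p = 0.058 in limma) and by fry (0.14), and the call of the oxidation list without any 1 array other than MSG array 2 (adjusted p between 0.051 and 0.28), with the 75th percentile filter (0.11) and with the replicate block (0.051).

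On the trans-fat/HFCS diet against control (2 arrays each), the 5 largest named increases were those of skeletal muscle genes. MYL1 rose 9.6-fold (log2 3.26, SE 0.18), MYH1 8.63-fold (3.11, SE 0.16), SLN 7.35-fold (2.88, SE 0.24), ACTA1 7.24-fold (2.86, SE 0.17) and TPM2 5.69-fold (2.51, SE 0.19). ID2B (log2 -2.50, SE 0.24), OSGIN2 (-2.33, SE 0.18), CEL (-2.29, SE 0.21), IL19 (-2.21, SE 0.27) and ACAT2 (-2.03, SE 0.30) fell. With its brightest probe set TPM2 did not pass (log2 0.22), and ID2B rests on probe sets at -4.89 and -0.10. The change of ID2B was -1.55 without control array 2. Camera in limma called the cholesterol list lower (adjusted p of 3.9e-07), but not with an estimated correlation (adjusted p = 0.12). Its median was -0.41, with 4 of 20 members down, none up and 8 lower when adjusted over the list alone. DHCR7 (log2 -1.77, SE 0.18), EBP (-1.24, SE 0.17) and the sterol demethylase CYP51A1 (-1.14, SE 0.24) fell besides ACAT2.

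limma called 444 genes here at a Benjamini-Hochberg adjusted p under 0.05, 262 higher and 182 lower, with adjusted p between 0.0001 for MYH1 and 0.012 for ACAT2 among the 10 genes named by the rule. Fatty acid and triglyceride synthesis genes had a median of -0.39 (-0.20 without the filter on dim probe sets) and a camera adjusted p of 0.00061 in limma (adjusted p = 0.18 with an estimated correlation). ACLY (log2 -1.19, SE 0.19) and an acetyl-CoA carboxylase, ACACA, fell, 9 of 22 were lower when adjusted over the list alone, and ME1 (-0.82, SE 0.18) and FASN (-0.78, SE 0.17) did not pass. The fatty acid call ended with the 75th percentile filter (adjusted p = 0.055 in limma). With the skeletal muscle genes left out after the data were seen, 397 genes passed. Leaving out any 1 control or trans-fat/HFCS array left between 65 and 113 genes.

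**Figure D3:**
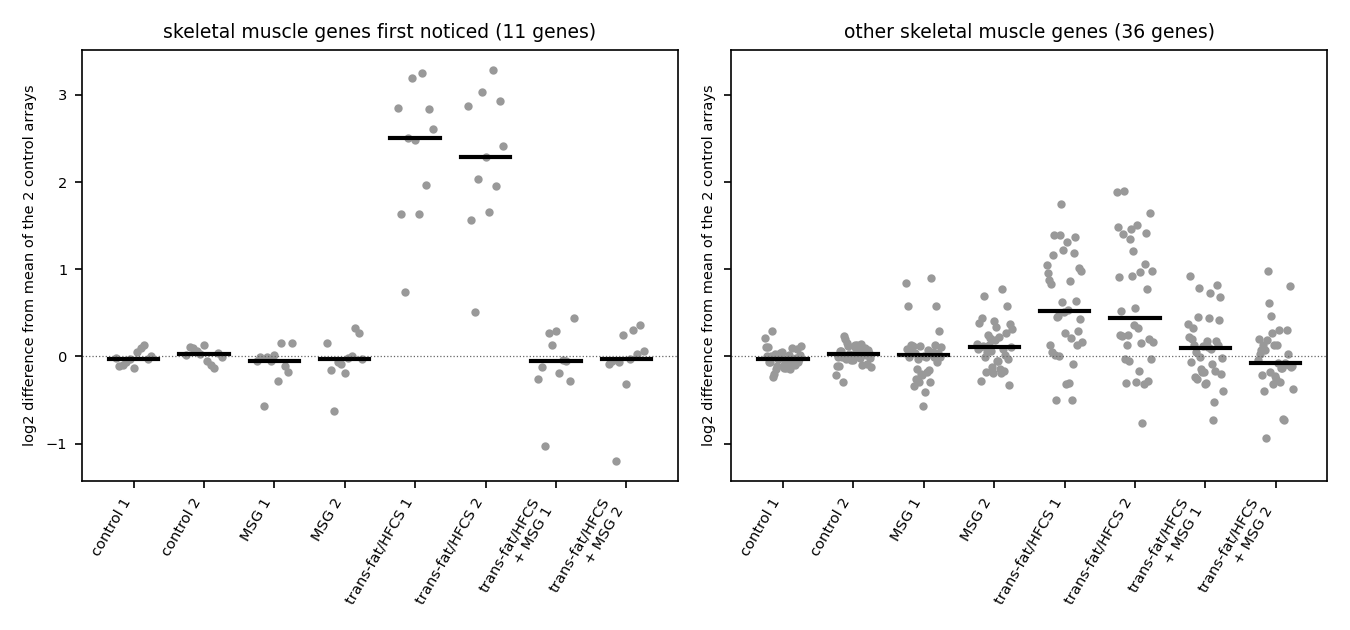
Log2 difference of each gene from the mean of the 2 control arrays (vertical axis) on each of the 8 arrays (horizontal axis), for 11 skeletal muscle genes noticed first (left) and 36 other skeletal muscle genes (right). Grey points are genes and black bars medians, which on the left are 2.50 and 2.29 on the trans-fat/HFCS arrays and lie within 0.06 of 0 on the other 6.

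On the combined diet against control (2 arrays each), FST rose 4.21-fold (log2 2.08, SE 0.17), TDRD5 3.45-fold (1.79, SE 0.25), ZAR1 3.42-fold (1.78, SE 0.27), ZBTB6 2.83-fold (SE 0.21 on the log2 scale) and the ion channel MCOLN2 2.81-fold (1.49, SE 0.17). OSGIN2 (log2 -2.22, SE 0.18), IL19 (-2.21, SE 0.27), ID2B (-1.92, SE 0.24), HP (-1.73, SE 0.30) and GADL1 (-1.72, SE 0.29) fell. The change of ID2B was -1.29 without control array 2 and -1.32 without MSG array 1. Camera in limma called the immediate early and the cholesterol list lower, each with an adjusted p of 1.8e-05, but neither with an estimated correlation (adjusted p = 0.15 for each). Of the immediate early genes 4 of 17 fell and none rose, with 7 lower when adjusted over the list alone and a median of -0.55. The 4 were ZFP36 (log2 -1.93, SE 0.17), FOS (-1.38, SE 0.19), FOSB (-1.52, SE 0.24) and DUSP1 (-1.11, SE 0.17). Without combined-diet array 1 the median was -0.21 (camera adjusted p = 0.00072 in limma), and without the filter on dim probe sets -0.34. Cholesterol synthesis genes had a median of -0.46 (-0.28 without that filter), with 3 of 20 down and 8 lower when adjusted over the list alone. DHCR7 (log2 -1.57, SE 0.18), ACAT2 (-1.62, SE 0.30) and EBP (-1.33, SE 0.17) fell, and IDI1 (-0.95, SE 0.24) did not pass.

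In limma, 207 genes passed here at a Benjamini-Hochberg adjusted p under 0.05, 103 higher and 104 lower. Adjusted p among the 10 genes named by the rule lay between 0.0051 for FST and 0.038 for HP in limma. Fibrosis and stellate cell markers had a median of -0.27, with SPARC the 1 member that fell (log2 -0.88, SE 0.16) and 3 lower when adjusted over the list alone. COL3A1 (-0.63, SE 0.16), PDGFRB (-0.68, SE 0.18) and COL1A2 (-0.51, SE 0.16) did not pass. Their camera adjusted p was 0.00035 in limma, and the adjusted p = 0.15 with an estimated correlation. In ZBTB6, ID2B and GADL1 1 of 2 probe sets moved over 8-fold and the other by -0.10, 0.01 and -0.13, and with its brightest probe set alone ZBTB6 turned sign. Probe sets also differed in TDRD5 (3.09 and 0.49), ZAR1 (2.94 and 0.61) and HP (-2.98 and -0.48), and in MCOLN2 6 of 9 rose, 2 of them over 8-fold. Without the filter on dim probe sets TDRD5 (0.24), IL19 (-0.65) and GADL1 (-0.27) did not pass. No gene passed in limma without control array 2 (1997 had an unadjusted p under 0.05), 14 passed without control array 1, between 61 and 110 without 1 array of the MSG or the combined diet, and 25 with only the 4 arrays compared. The 3 comparisons with control share its 2 arrays, so OSGIN2 and FST, which differed from control on each diet, rest on the same control values.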

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

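The test of skeletal muscle genes on the combined against the MSG diet and the ratio of array differences within 1 base diet were chosen after the result was seen, and the bounds of the other tests were set before their values were seen.

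The MSG effect differed between the base diets in 27 genes by the interaction test in limma. The differences were 3.10 for TMEM41A, 2.29 for OSGIN2, 2.16 for SLC25A21, 1.99 for BEGAIN and 1.94 for SLC15A3. They were -3.21 for MYL1, -3.08 for ACTA1, -2.89 for SLN, -2.85 for MYH1 and -2.83 for GSTA3. The interferon response list had a median difference of -0.33. Of 16926 kept probe sets without a single gene name, which no comparison used, 951 (5.62%) passed for the trans-fat/HFCS main effect.

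All 35 splits of the 8 arrays into 4 and 4 were fitted with the split as the only factor. The real trans-fat/HFCS split called 1104 genes and the highest other split 1, so 1 of 35 splits gave as many and chance can be excluded at that share if the 8 arrays are independent. With the 2 arrays of a diet kept together, as kin or a shared dam would require, only 3 splits exist, too few for a share under 0.05. The MSG split called 1 gene, and 4 splits, the trans-fat/HFCS split with 1104 among them, called as many, so chance cannot be excluded for MSG by this test, in which the base-diet difference stays in the residual spread. That the trans-fat/HFCS split calls so many more points to a structure of the samples that follows the base diet.

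Skeletal muscle genes were high on both trans-fat/HFCS arrays. Of the 36 muscle genes not noticed first, the 12 that rose there had a median of 1.31. On the combined against the MSG diet, with no array shared, their median was 0.04. In these 12 genes the values argue against an effect of trans fat and HFCS whatever the MSG. The 95% interval of the 0.04 (-0.09 to 0.15) resamples genes, so it does not measure the spread between cats. As the 12 were picked for their rise, 1.31 may be too high. Of the 36 other skeletal muscle genes, 14 of them above the median gene in control liver and none in the fixed lists, these 12 rose and none fell, with a camera adjusted p of 3.5e-10 in limma (adjusted p = 0.02 with an estimated correlation). The median of 0.44 over the 36 narrowly missed the bound of 0.5 set beforehand for muscle tissue in the samples. CKM rose by 1.29 to a mean of 6.88 and TNNC2 by 1.38, while MB (-0.02) and ENO3 (-0.40) were not higher. MB was dim, at a mean of 3.06 on control against a filter floor of 2.43. Dimmer members went both ways: CKMT2, at 2.61 on control, rose by 1.64, and MYOT, at 2.54, did not pass (0.44). A low control value therefore did not by itself prevent a rise. On both trans-fat/HFCS arrays, 26 of the 36 were higher than on either control array. Muscle tissue therefore cannot be told apart from other explanations by this test. Smooth muscle, with a median of 0.42, none past the threshold and 6 of 9 genes higher on both arrays, stays open too. Its test reads smooth muscle genes only, so it does not show whether smooth muscle could account for the rise of the skeletal ones. An effect of this diet that needs the absence of MSG was not tested.

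Between base diets 273 probe sets moved over 8-fold, and in the 258 whose gene had at least 2 others, the others moved by a median of 0.01 of the jump (95% interval 0.00 to 0.02, resampled over probe sets). This is what a sequence difference between cats under a probe set would give, so it may underlie part of the calls. The ratio cannot tell it from a change in expression that the other probe sets, with cat RNA on human probes, read poorly. Picking probe sets for their jump also lowers the ratio. Of the 1372 genes called for the main effect, 115 held a probe set with such a jump, as did 262 of all 17910 genes tested. Another measure is that 261 of the 1372 rested on 1 kept probe set. Genes with 1 were called more often (13%) than genes with more (6.98%). Few jumping probe sets had others that moved with them: in 1 of the 258 the others moved by most of the jump. Beside the jump of -3.15 in ACAT2 the others had a median of -1.87. In MYH1 4 probe sets jumped, the largest by 3.90, beside which the others had a median of 0.84. Sharing of RNA or close kin within a diet stays open, as arrays of 1 diet differed over 8-fold at 0.43 times as many probe sets as arrays of different diets, and at 0.69 times as many as arrays of the other diet on the same base (ranges 230 to 716 and 494 to 847 probe sets). Differences between single cats falling on the diets at random also stay open, since the highest of the other 34 splits, the MSG split with 78, reached 0.29 of the real count, and a diet effect on single exons was not tested.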

How the results depend on the processing

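Settings that left out the trans-fat/HFCS diet, the skeletal muscle genes, genes with no cat symbol or genes with 1 kept probe set were chosen after seeing the data. Of the 6 gene counts, those for the trans-fat/HFCS main effect stayed within 1.5 times of 1372 in 13 of 18 alternatives, those leaving out 1 array not counted. The MSG main effect did so in 11 of 18, the interaction in 8 of 15, the MSG diet in 10 of 16, the trans-fat/HFCS diet in 9 of 16 and the combined diet in 8 of 16. Quantile normalization, median centring, no filter on dim probe sets and a 1.5-fold minimum moved none of the 6 counts by over 1.5 times. Outside the trans-fat/HFCS main effect every called gene already differed by at least 1.5-fold, so that minimum could not change the count. The arrays already had close medians, which left the 2 normalizations little to change. Except where a setting's construction shows it, the cause was not tested. Low signal over background, with cat RNA on human probes, limits what genes near the filter floor can show.

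In the order trans-fat/HFCS main effect, MSG main effect, interaction, MSG diet, trans-fat/HFCS diet and combined diet, the median of a gene's probe sets gave 595, 13, 5, 15, 180 and 44 genes. The brightest probe set gave 2182, 106, 56, 102, 1120 and 730, with 68.6% of calls higher for the first against 58%, and 75% for the interaction against 40.7%. Tested singly, 2734, 169, 69, 134, 1035 and 72 probe sets passed. An adjusted p under 0.10 in limma gave 2440 and 105 for the main effects and 1016 and 578 for the trans-fat/HFCS and combined diets. A trend with a robust prior gave 92, 47, 81, 684 and 413 for the last 5, and the 75th percentile filter 14, 95, 834 and 513 for the last 4. Array weights gave 694 for the trans-fat/HFCS diet, and only the 4 arrays compared gave 25 for the combined diet. The MSG main effect fell to 1 gene with MSG as the only factor and to 1 in the additive model, where the interaction enters the residual spread. Without the trans-fat/HFCS diet, the combined against the MSG diet gave 228 genes in a fit of 6 arrays, against 297 in a fit of all 8. Without skeletal muscle genes 12 passed for the interaction.

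Leaving out 1 array at a time gave 436 to 1232 genes for the trans-fat/HFCS main effect, 15 to 70 for the MSG main effect, 5 to 21 for the interaction, 14 to 55 for the MSG diet, 65 to 540 for the trans-fat/HFCS diet and 0 to 146 for the combined diet. For the trans-fat/HFCS main effect every array but combined-diet array 2 moved the count by over 1.5 times (436 to 867). For the MSG main effect all but trans-fat/HFCS array 2 (41) and combined-diet array 2 (70) did (15 to 39), and for the interaction all but the combined-diet arrays (5 to 17). For the MSG diet the control and MSG arrays did (14 to 20), for the trans-fat/HFCS diet the control and trans-fat/HFCS arrays (65 to 113). For the combined diet the control arrays (14 and 0), the MSG arrays (96 and 79) and its own arrays (61 and 110) did. The count of 0 in limma came without control array 2, where 1997 genes had an unadjusted p under 0.05. The lone array of a diet is then assumed to vary like the other diets. Camera called 4 to 5 lists for the trans-fat/HFCS main effect and 0 to 1 for the MSG main effect, the 1 without MSG array 2 or combined-diet array 2 (3 at an unadjusted p under 0.05 with all arrays, and 0 by fry).

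The replicate number does not pair the arrays: deviations of same-numbered arrays correlated between -0.06 and 0.04 over the 6 pairs of diets, and the labels number different cats. With it as a replicate block, 1026, 53, 11, 34, 299 and 96 genes passed.

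For the trans-fat/HFCS main effect camera called 4 lists, 2 with the 75th percentile filter (cholesterol synthesis and 1 list outside the 4) and 0 with an estimated correlation (4 at an unadjusted p under 0.05), and fry called 8. For the MSG main effect 1 list was called without the trans-fat/HFCS diet. All 12 list results kept their direction in every setting run.

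Named genes kept their direction except MYBPC1 in the MSG main effect (0.36 with the 75th percentile filter), KBTBD10 in the MSG main effect (0.71 with the brightest probe set) and ZBTB6 on the combined diet (-0.10 with the brightest probe set). Without the trans-fat/HFCS diet, which leaves the MSG diet against control, ACTA1 (0.07), SLN (0.04) and MYBPC1 (0.15) also turned sign. The arrays carrying these genes were then left out. In every setting that scored them, 6 of 24 named genes kept their call for the trans-fat/HFCS main effect (CYP7A1, FCER1G, FKBP5, GADL1, HP and ID2B). For the trans-fat/HFCS diet 5 of 10 did (ACTA1, MYH1, MYL1, OSGIN2 and SLN). For the MSG diet 2 of 10 did (FST and OSGIN2), and none of the 17, 10 and 10 did for the MSG main effect, the interaction and the combined diet. Probe sets tested singly scored none by name, the 75th percentile filter 75 of 81 entries. Without skeletal muscle genes ACTA1, MYH1, MYL1 and SLN were unscored. With 2 probe sets (FCER1G, GADL1, HP, ID2B, SLN) the median changed no value, and calls of GADL1 and ID2B rest on 1.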

Other observations

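The lists were fixed before the data were examined, and those described first were chosen after their values were seen. With trans fat and HFCS, their genes moved in both directions and camera called none of them. Of 22 measured bile acid genes, CYP7A1 and CYP7B1 fell (log2 -1.57 and -0.73) and NR0B2, a nuclear receptor that represses CYP7A1, rose by 0.56 (SE 0.13). The camera adjusted p was 0.24 in limma. Of 24 genes of fructose and glucose breakdown, 2 rose and 5 fell in limma: ALDOA (log2 0.69, SE 0.13) and TALDO1 (0.57, SE 0.12) rose, and PFKFB3 (-0.49, SE 0.11) and PFKFB1 (-0.55, SE 0.13) were among those that fell, with a camera adjusted p of 0.62. In the insulin and IGF list, IGF1 (log2 -0.56, SE 0.11) and FOXO1 (-0.46, SE 0.12) fell while TRIB1 (0.56, SE 0.11) and FOXO3 (0.50, SE 0.11) rose, with a camera adjusted p of 0.45.

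Of 17 macrophage and Kupffer cell markers, CD68 (log2 0.78, SE 0.14) and MSR1 (0.50, SE 0.13) rose and FCER1G fell (-1.55, SE 0.21), with a camera adjusted p of 0.45 in limma. Among 19 circadian clock genes, HLF (log2 0.69, SE 0.12) and NPAS2 (0.55, SE 0.12) rose and BHLHE40 fell (-0.75, SE 0.16), with a camera adjusted p of 0.92. Of 26 fatty acid oxidation genes and PPARA targets, VNN1 (log2 1.80, SE 0.25) and ANGPTL4 (0.61, SE 0.13) rose and CPT1A fell (-0.60, SE 0.12), with a camera adjusted p of 0.92.

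For trans fat and HFCS camera called 4 of 35 lists in limma, and the lowest adjusted p among the other 31 was 0.073. That was endoplasmic reticulum stress, with a median of -0.16. Median log2 changes were -0.08 for lipid droplets, -0.10 for lipoproteins, -0.10 for gluconeogenesis and glycogen, -0.01 for glutamate, -0.03 for the urea cycle and amino acids, 0.09 for drug metabolism and 0.03 for oxidative stress. They were 0.02 for heat shock, 0.05 for acute phase, 0.01 for inflammatory signalling, -0.03 for interferon response, 0.18 for cell cycle, -0.06 for oxidative phosphorylation, 0.10 for ribosomal proteins, -0.04 for the proteasome and -0.06 for coagulation. Among cell type markers they were -0.07 for lymphocytes, -0.14 for neutrophils, 0.24 for erythroid cells, 0.02 for endothelium, -0.07 for cholangiocytes, 0.03 for hepatocytes, 0.09 for adipocytes and 0.14 for pancreas.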
